A study of Picea glauca with 42 samples.

How the data were processed

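Total RNA from needles of white spruce (Picea glauca) was amplified, labelled with Alexa 647 and hybridised to a custom spruce oligonucleotide array, 1 sample per array, per the labels. The 42 arrays came from 14 trees, 7 resistant and 7 non-resistant to budworm, and each tree gave 3 needle samples, from the top, the left and the right, per the labels. The arrays per class number 21.

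The authors deposited 1 scanner file per array, with the intensity of each spot on a linear scale, its local background and the net intensity, per the file headers. The net intensity was the raw mean intensity minus the trimmed-mean background in every file, as tested on the values. The headers name the 532 channel although the dye in the labels is Alexa 647; the scanner columns were used as given, and which channel they hold stays unsettled. Each array had 34992 spots, of which 32144 were spruce probes with 1 spot each and 2848 were controls. The design text names probes for 23853 genes, and the files used here do not pair probe IDs with genes. Gene lists that had been fixed beforehand could therefore not be formed and the gene list tests were not run. Up to a pair of probe IDs per direction were named.

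The deposited value table of the series holds log2 values, as its comparison with the scanner files showed, and its processing is not given in the sources used here. Column medians over spruce probes ran from 6.66 to 6.90. The values matched log2 net intensity, with values at or below 0 set to 0 on the log2 scale, after quantile normalization: each column reached a Pearson r of at least 0.9998 across probes with 1 scanner file. For 41 of the 42 columns that file belonged to another sample than the column's name says. Scanner files, assigned to samples as deposited, were the source of the main values, as fixed beforehand. The value table under its own labels served as a second source of values, as fixed beforehand, and no column was reassigned. Chosen after seeing the data were fits with the recipe of the table applied to the scanner files and a fit without the 2 arrays least like the others. No column of per-sample values was left out.

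In R 4.3.3 with limma 3.58.1, raw mean intensity was background corrected with normexp (offset 50), quantile normalized between arrays over all spots and analysed as log2 values. Control spots were then left out and no spruce probe was filtered. Saturated spots, 4 over all arrays, were kept. A probe counted as above controls on an array where its net intensity exceeded percentile 95 of the 1574 empty, blank and buffer spots of that array. This depends on the array, because that threshold ran from 4.22 to 83.3. The number of arrays limits the precision.

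The tree was taken as the replicate. Tree numbers come from the labels and mark 1 individual, so the 3 arrays of a tree were averaged for the comparison of the resistance classes, and tree was a fixed block for the comparisons of positions. The same class comparison was also made within each position. The interaction compared the difference of top minus the mean of left and right per tree between the classes. All tests were two-sided limma fits with empirical Bayes moderation over 32144 probes, called at a Benjamini-Hochberg adjusted p under 0.05. Exact permutation tests over the splits of the trees were given for single probes. The share of variance between trees was estimated with duplicateCorrelation. The rule for named probes was fixed before the data were examined: those past the threshold, or, with fewer than 10 past it, those with the smallest p in each direction with values only, and, with no pairing of probes and genes, at most 2 that rose and 2 that fell. Positions and the interaction name only probes past the threshold, except that Spruce_16624, chosen after its values were seen, is followed through single positions and the interaction.

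Alternatives fixed before the data were examined were no background correction, median scaling, cyclic loess, the value table, a filter for probes above controls on at least 7 arrays, scan day as a covariate, trend and robust settings of the moderation, all arrays with tree as a random block, array weights, a minimum fold of 2, fits of position without the tree block, and each tree left out in turn. The arrays fell on 8 scan days and all carried 1 slide batch in the labels. Each label shuffle or split used a fixed seed.

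The fits were tested on simulated data with the measured probe means and spread and 200 probes changed, 50 per size. For resistant against non-resistant trees over 32144 probes, 44% of the probes changed by 0.5 on the log2 scale were recovered, 94% at 1 and 98% at 2. With 200 probes changed at once the adjusted p is easier to pass than with 1 changed probe. The simulated spread was also equal in both classes. These shares therefore do not tell how often a lone difference would be found. With no probe changed, that comparison made 0 calls. The fit with tree as a random block over 32144 probes made 39 calls when no probe was changed. Each of these counts comes from a single draw, with probes drawn independently of each other and without scan day effects. Measured probes can vary together, so their counts can spread more widely.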

Results

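Needle transcript levels were measured in 14 white spruce trees, 7 resistant and 7 non-resistant to the spruce budworm, a defoliating moth larva. Each tree was sampled at the top, on the left and on the right, which gave 42 single-dye arrays with 32144 spruce probes. Median net spot intensity per array ran from 67.2 to 157.8. Its mean was 101.1 ± 18.4 (SD, n = 21 arrays) in the non-resistant class and 106.0 ± 25.4 (SD, n = 21 arrays) in the resistant class. Between 49.4% and 88.5% of spruce probes lay above the threshold of the empty, blank and buffer spots on an array, with a median of 81.2%. Of the 32144 probes, 14428 were above controls on all 42 arrays. The files do not pair probes with genes, so probes are given by ID.

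Samples of 1 tree resembled each other. For 29 of the 42 arrays the most similar array came from the same tree, against at most 13 in 10000 shuffles of the tree labels. Some arrays of a tree shared a scan day. Among arrays of other scan days only, the nearest was of the same tree for 21 of the 39 arrays with such a partner, against at most 12 in 10000 shuffles within scan days. The median Pearson r across probes was 0.954 between arrays of the same tree and 0.936 between arrays of other trees; probes are not independent replicates. The consensus correlation within trees, after class and position, was 0.20, and the per-probe median was 0.17. It exceeded 0.5 for 5836 probes, or 18.2%, and 0.8 for 1056 probes.

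The main question was which transcripts differ between resistant and non-resistant trees. By size, Spruce_16624 stood apart. Its normalized log2 intensity was 12.87 ± 2.51 (SD, n = 7 trees) in resistant trees and 6.68 ± 0.06 (SD, n = 7 trees) in non-resistant trees. On this scale, which includes the normexp offset of 50, the log2 difference was 6.18 with a standard error of 0.90 and a 95% interval from 4.25 to 8.12. Median net intensity was 17808 in resistant and 12.2 in non-resistant arrays. All 21 resistant arrays exceeded all 21 non-resistant arrays, with lowest resistant and highest non-resistant log2 values of 7.54 and 7.02. The probe was above controls on 21 resistant arrays and on 9 of 21 non-resistant arrays, so its non-resistant level was near background and no fold is given. The log2 difference was 6.14 without background correction. The two-sided exact permutation p over trees was 0.000583, the smallest that 7 against 7 trees can give. Over all probes it did not pass: the limma adjusted p was 0.106. Without tree 19 it passed, with a difference of 7.03 and a limma adjusted p of 3.28e-05. It also passed with array weights (limma adjusted p 0.0385), with tree as a random block (limma adjusted p 5.37e-09), and with the recipe of the value table applied to the scanner files, where the difference was 9.65 (limma adjusted p 0.00353). That recipe has no offset, so its size rests on non-resistant values near background. The probe did not pass with median scaling (limma adjusted p 0.0620), cyclic loess (0.143), trend and robust settings (0.0580) or the filter on dim probes (0.0886). Nor did it pass with any other single tree left out. In the value table under its own labels the difference was 2.41. The random block assumed a correlation within trees of 0.20 for all probes, against 0.87 for this probe after class and position, so its p is too small.

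**Figure D1:**
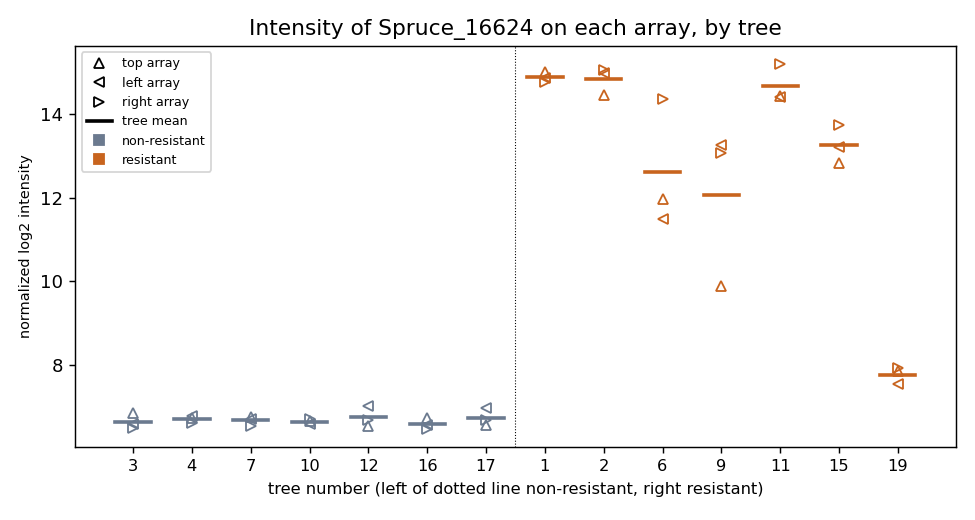
Normalized log2 intensity of Spruce_16624 on each array (y axis) by tree number (x axis), with non-resistant trees left and resistant trees right of the dotted line. Triangles are top, left and right arrays and bars are tree means; non-resistant tree means lie between 6.60 and 6.75, resistant ones between 7.77 and 14.88.

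Resistant trees spread widely for Spruce_16624. Tree means were 14.88 in tree 1, 14.83 in tree 2, 14.67 in tree 11, 13.25 in tree 15, 12.60 in tree 6, 12.07 in tree 9 and 7.77 in tree 19. In tree 9 the top array read 9.88 and the side arrays 13.25 and 13.07. The lowest resistant net intensity was 77.5 and the highest non-resistant one 40.6. In the 6 scan days that held both classes, class means differed by 4.10 to 8.26. These days were thin, with 1 array of each class on day 8. With scan day as a covariate and tree as a random block the difference was 6.71 (limma adjusted p 1.34e-07, too small for the same reason). With scan day as a covariate and the classes permuted over trees, it was 6.75, with a two-sided exact permutation p of 0.000583.

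With limma on tree means, 1 of 32144 probes passed. Spruce_20911 rose in resistant trees, from 7.19 ± 0.11 to 7.67 ± 0.09 (SD, n = 7 trees each). The difference was 0.48 on the log2 scale with the offset (standard error 0.05), or 1.39-fold on that scale. The limma adjusted p was 0.0194. The offset draws differences of dim probes toward 0, and the ratio of the class medians of net intensity was 1.83. Arrays within a tree had an SD of 0.31. Means of 3 such arrays would vary more than these tree means did, so the standard error is probably too small. Tree means did not overlap: the highest non-resistant was 7.32 and the lowest resistant 7.58. Single arrays did overlap, and median net intensities were 57.4 in non-resistant and 105.2 in resistant arrays. On the 6 scan days with both classes Spruce_20911 differed by 0.16 to 0.67, higher in resistant arrays each time. The probe was picked on these same arrays, so this is no independent test. With scan day as a covariate and tree as a random block the difference was 0.36 and did not pass (limma adjusted p 0.335). The call was also lost when tree 2, 4, 6, 9, 10, 12 or 16 was left out, with differences of 0.46 to 0.48. It was lost with median scaling (0.49), cyclic loess (0.48) and the trend and robust settings (0.48), at nearly the same size. With the recipe of the value table on the scanner files the difference was 1.06 (limma adjusted p 0.0923), and in the value table under its own labels it was 0.08. The number of calls was 3 without tree 3 and 2 without tree 15 or tree 19.

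Among probes lower in resistant trees, none passed. The smallest p belonged to Spruce_01296, at 8.38 ± 0.25 in non-resistant and 7.61 ± 0.26 in resistant trees (SD, n = 7 trees each), a difference of -0.78 (standard error 0.13, limma adjusted p 0.246). Its tree means overlapped, and its exact permutation p was 0.00117. Spruce_09640 had 7.24 ± 0.08 and 6.98 ± 0.06 (SD, n = 7 trees each), a difference of -0.25 (standard error 0.04, limma adjusted p 0.246). Both were lower in resistant arrays on each of the 6 scan days with both classes. This is no independent test, since they were picked for small p on these same arrays. Spruce_01296 differed there by -1.13 to -0.35 and Spruce_09640 by -0.69 to -0.04. With scan day as a covariate and tree as a random block, Spruce_01296 differed by -0.78 (limma adjusted p 0.00531) and Spruce_09640 by -0.31 (limma adjusted p 0.0319), and both passed. With tree as a random block alone, Spruce_01296 passed (limma adjusted p 9.84e-05) and Spruce_09640 did not (limma adjusted p 0.0866). Both of these fits assumed 1 correlation within trees for all probes. They can understate the error of a probe that varies between trees. The share of variance between trees, class difference included, was 0.74 for Spruce_01296 and 0.15 for Spruce_09640. The latter lies below the 0.20 assumed without scan day, so that reason does not apply to Spruce_09640 there. Its arrays within a tree had an SD of 0.21, so its standard error on tree means is probably too small, as for Spruce_20911. On tree means neither probe passed. With the recipe of the value table on the scanner files, Spruce_01296 differed by -1.29 (limma adjusted p 0.296) and Spruce_09640 by -0.72 (limma adjusted p 0.305). In the value table under its own labels, Spruce_01296 turned to 0.12.

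**Figure D2:**
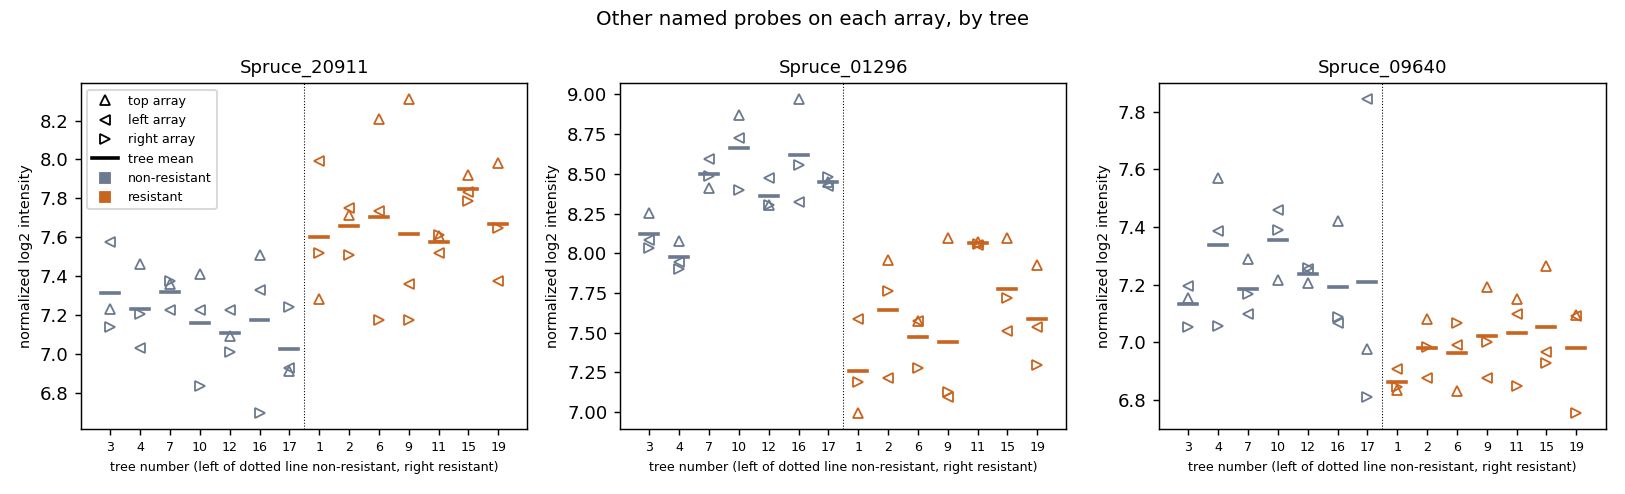
Normalized log2 intensity of Spruce_20911, Spruce_01296 and Spruce_09640 on each array (y axes) by tree number (x axes), with non-resistant trees left and resistant trees right of the dotted lines. Triangles are arrays and bars tree means; single arrays of the classes overlap for all 3 probes.

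On this scale, which includes the normexp offset of 50, large differences were few. The offset draws differences of dim probes toward 0, so differences in net intensity can be larger than those counted here. A difference of at least 1 on the log2 scale was seen for 51 probes with higher and 71 with lower means in resistant trees, and of at least 2 for 12 and 1 probes. At an unadjusted p under 0.05 there were 2558 probes, 1180 higher and 1378 lower in resistant trees, where 1607 would come by chance. Tree means of the classes did not overlap for 43 probes, 19 higher and 24 lower, against 18.7 by chance. Of these, 2 differed at least 2-fold. Spruce_16624 was the 1 probe whose 42 single arrays also separated. With tree as a random block on all 42 arrays, limma called 196 probes, 94 higher and 102 lower in resistant trees, 31 of them at least 2-fold. That fit made 39 calls in a single data set simulated without any change, with probes drawn independently. With scan day added as a covariate it called 42 probes, 20 higher and 22 lower.

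Within single positions limma called 0 probes. Unadjusted p under 0.05 was reached by 1311 probes at the top, 2333 on the left and 1521 on the right, with 1607 by chance. Spruce_16624, followed here after its values were seen, was 5.65 higher in resistant trees at the top (limma adjusted p 0.402), 6.07 on the left (limma adjusted p 0.424) and 6.83 on the right (limma adjusted p 0.0989). It ranked first by p on the left and right and at place 2 at the top. With the recipe of the value table applied to the scanner files, chosen after seeing the data, it passed in all 3 positions.

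Comparing positions within trees asked how needles of 1 tree differ. Top against sides gave 0 calls by limma (smallest adjusted p 0.622), with 1908 probes at an unadjusted p under 0.05, 1187 higher and 721 lower at the top. Left against right gave 0 calls (smallest adjusted p 1.00), with 710 probes at an unadjusted p under 0.05. The median standard error was 0.07 and 0.08 on the log2 scale. Without tree 7 the count for top against sides was 1.

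The difference of the top effect between the classes gave 0 calls by limma (smallest adjusted p 0.875), with 1174 probes at an unadjusted p under 0.05. For Spruce_16624, chosen after its values were seen, the top effect of resistant trees minus that of non-resistant trees was -0.80 (standard error 0.43, limma adjusted p 0.875). In simulated data with 200 probes changed at once, this comparison over 32144 probes recovered 30% of probes changed by 0.5 and 84% of those changed by 1 on the log2 scale.

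The value table was set against the scanner files. Each of its 42 columns matched 1 scanner file with a Pearson r across probes between 0.99981 and 0.99995, while the next best file reached at most 0.954. In 41 columns the match was the file of another sample, and in 18 of a sample of the other class.

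**Figure D3:**
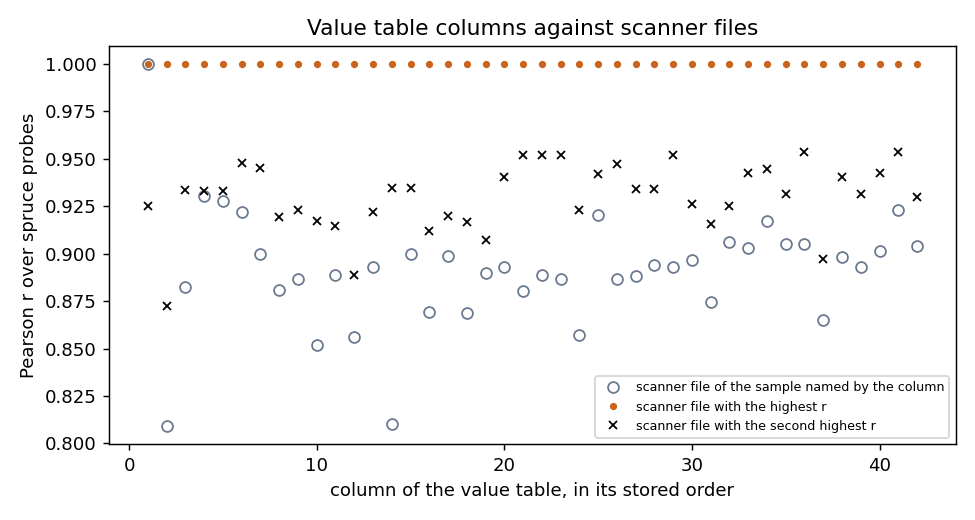
Pearson r across spruce probes (y axis) between each value table column, in stored order (x axis), and scanner files. Circles are the file of the sample that names the column, dots the file with the highest r and crosses the second highest; 41 of 42 circles lie apart from the dots.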

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

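The tests of scan day, background and probe sequence for Spruce_16624 and the tests of slide order and of wrong labels for the value table were chosen after the results were seen. The counts of splits, the test of the random block and the test of shared scan days were set down before their own results were seen. The fits had by then been run once on the real data.

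Resistant tree 19 stood apart from the other resistant trees for Spruce_16624, at 7.77 against 12.07 for the next lowest tree. The class difference of this probe was weighed against technical explanations. Scan day is argued against, since the class difference did not shrink when adjusted for scan day: it was 6.75, against 6.18 unadjusted. The two-sided exact permutation p over the trees was 0.000583, with 6.28 as the highest other split after adjustment. For this picked probe that p was already the smallest possible without adjustment, so it is no separate test of scan day. Weak signal in both classes was not seen, since 21 of 21 resistant arrays lay above the control threshold. A probe picked for its large difference could hardly have shown it, so this is a description and not a test. The largest class difference over all probes was 6.18, and 1 of 100 splits of the trees reached it, the real one, with 4.64 as the highest other. Chance is thus argued against to no finer than 1 in 100, for a difference already seen when the test was set down. On tree means the probe did not pass over all probes (limma adjusted p 0.106). A sequence variant under the probe stays open: resistant tree means spanned 7.10 on the log2 scale, which is more than 1 shared level, but the probe sequence was not used here. A difference in expression that goes with the resistance class is a further open explanation, and relatedness of the trees was not tested.

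The value table and the scanner files disagree on which array belongs to which sample. The table columns may have been stored in slide order under sample names in another order: 42 of 42 columns matched the array at the same place in slide order. Wrong labels on the scanner files are argued against, since 8 of 42 arrays had their nearest array in the same tree under the table labels, against 27 with the same recipe under the scanner file labels. Shared scan days do not account for the likeness of arrays of a tree: among arrays of other scan days only, the nearest was of the same tree for 21 of 39 arrays, against at most 12 in 10000 shuffles of tree labels within scan days, and for 1 of 18 columns under the table labels. No biological explanation was tested.

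With tree as a random block 196 probes were called, against 1 with tree means. Of 100 splits 1, the real one, gave as many, with 157 as the highest other and the within-tree correlation held at its real value. Chance is thus argued against to no finer than 1 in 100. The median of the other splits was 19 calls, and the same fit made 39 calls in a single data set simulated without any change. That data set had independent probes and no scan day effects, so it is a limited baseline. The splits did not keep the uneven spread of the classes over scan days. Day 4 held 6 non-resistant and 0 resistant arrays, and day 2 held 1 and 6. With scan day as a covariate the fit called 42 probes, 36 of them among the 196. Scan day therefore stays open for the others. A candidate explanation for the excess over tree means is that 1 correlation for all probes understates the error of probes that vary between trees: the median within-tree correlation of the called probes was 0.61, above the upper quartile of all probes (0.41) and the consensus of 0.20. Of the 196 probes, 13 had tree means without overlap. A true class difference in part of them stays open.

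For the following counts, the splits did not exclude chance. The single call between the classes was reached in 5 of 100 splits with the real one included (real 1, highest other 1), the 2558 probes at an unadjusted p under 0.05 in 6 with the real one included (highest other 2907) and the 43 separating probes in 7 with the real one included (highest other 58). A count of 0 is reached by every split or shuffle of position within trees, 100 of 100, by construction, so for these comparisons the splits test nothing. The highest others were 77 at the top, 1 on the left, 21 on the right, 2 for top against sides, 0 for left against right and 3 for the difference of the top effect. The 77 and the 21 calls came from 1 split each; what the trees of those splits share was not tested.

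A value apart from its group was found in 6 of 26 groups of 7, where 1.3 would come by chance. Besides tree 19 for Spruce_16624, the left array of non-resistant tree 10 had a median net intensity of 70.97, with 97.2 as the next. The left array of non-resistant tree 16 had 65.2% of probes above controls (next 76.1) and a median r with other arrays of 0.853 (next 0.927). The top array of resistant tree 1 had 73.9% (next 82.6), and the right array of resistant tree 19 a median r of 0.911 (next 0.936). In the control spots, not used in the comparisons, 93.5% of GFP spots and 36.1% of Alien spots exceeded the threshold of the negative controls. Of the spots that set the threshold, 15.9% of blank, 5.96% of buffer and 2.55% of empty spots exceeded it. Since the threshold is percentile 95 of these same spots pooled, a small share of them exceeds it by construction. Being above controls was thus seen for GFP and Alien spots as well as spruce probes. Whether the GFP and Alien spots had a target in the samples was not tested.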

How the results depend on the processing

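The value table recipe and the fit without the 2 arrays least like the others were chosen after seeing the data; the rest were planned. The count of calls between the classes, 1 with tree means, was 0 with median scaling, cyclic loess, the value table as labelled, trend and robust settings and a minimum fold of 2, 2 with array weights and 42 with scan day as a covariate and tree as a random block. The replicate block as a random effect on 42 arrays gave 196 calls, which include Spruce_20911 and Spruce_16624. Leaving out each tree in turn gave 0 to 3 calls between the classes and 0 to 1 for top against sides. It was 1 without background correction, with the filter on dim probes, with the value table recipe (then Spruce_16624) and without the 2 arrays least like the others. Within positions, median scaling gave 1 call on the right, and the value table recipe 1 at the top, 1 on the left and 2 on the right, Spruce_16624 among them each time. For top against sides and left against right, the fit without the pairing by tree also gave 0 calls. The other alternatives run for positions and the interaction gave 0; array weights, the minimum fold, the random block alone and leaving out 2 arrays were run only for the comparison of the classes over all positions. Separating probes, 43, numbered 23 with median scaling, 8 in the value table, and 48 both without background correction and with the value table recipe. The correlation within trees, 0.20, was 0.174 with median scaling, 0.108 in the value table and 0.192 with its recipe. Spruce_16624 kept its direction in 25 of 25 alternatives (2.41 to 9.65; adjusted p 5.37e-09 to 1.00) and passed in 5. Spruce_20911 kept its direction in 25 (0.08 to 1.06; adjusted p 0.00963 to 1.00) and lost its call in 13. Spruce_01296 reversed to 0.12 in the value table as labelled, where 41 of 42 columns match arrays of other samples. With the same recipe on the scanner files it was -1.29. With the recipe held the same, the table labels also gave lower values than the scanner files. Separating probes numbered 8 against 48, the correlation within trees was 0.108 against 0.192 and Spruce_16624 differed by 2.41 against 9.65. The recipe thus does not account for these changes, and they go with the assignment of columns to samples. For the changes in the other alternatives the cause was not tested. Gene list tests were not run, for want of a pairing of probes with genes. Signal over background limits dim probes: 28941 probes pass the filter.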

Other observations

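The relation of a second probe to Spruce_16624 was tested after its values were seen; the split count for tree-variant probes was set down before. Single trees differed strongly for a small set of probes. For 84 probes the tree means spanned at least 4 on the log2 scale, or 16-fold, with a share of variance between trees over 0.8. Spruce_16624 had the widest span of all probes on this scale, 8.28, with its lower end in non-resistant trees near background. Of the 84 probes, 1 separated the classes completely and 12 differed at least 2 on the log2 scale between them.

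The hypothesis that such probes divide with the resistance class more than with other splits of the trees was left open: their median absolute class difference was 0.79, and 5 of 100 splits, the real one included, gave one as large (highest other 0.89), so chance was not excluded.

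The probe with the second largest class difference was 4.09 higher in resistant trees (standard error 0.90, limma adjusted p 0.274). It was above controls on 11 of 21 non-resistant and 19 of 21 resistant arrays, so the non-resistant level of 6.72 was near background. Among the 7 resistant trees it followed Spruce_16624 with a Pearson r of 0.84 (exact permutation p 0.0117) and a Spearman rho of 0.75 (exact permutation p 0.0663). Without the 2 trees farthest from the median, r was 0.83 over 5 trees. After adjustment over 32143 probes, of which 753 had a larger absolute r, the exact permutation p was 0.917. The smallest p that 7 trees can give is 0.000198 and the smallest adjusted p of any probe was 0.87, so this correction could hardly be passed and chance is left open.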
